A study of Homo sapiens with 20 samples.

How the data were processed

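Total RNA from HCT-116 cells was extracted with TRIzol and DNase, depleted of ribosomal RNA and made into stranded libraries with a TruSeq total RNA kit, per the labels' protocols. The authors deposited 1 table of raw counts, whole numbers with no normalisation, over 41092 rows: 39918 genes with Ensembl identifiers and 1174 repeat subfamilies. Its 20 columns matched the 20 samples by name, and 0 columns were left out. The lowest row total was 1. The submitters' processing notes list FastQC, cutadapt 1.18, STAR and the build hg38, without roles. That these checked, trimmed and aligned the reads, in that order, is inferred here from the tools. The counting tool, the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Overlapping and antisense genes, near-identical copies (HSPA1A and HSPA1B, histones, metallothioneins) and young repeat subfamilies are therefore uncertain. Of rows with a total of at least 100, 28 held counts identical to another row. Names were matched for 39900 genes, and positions for 38661 were taken from GENCODE release 29 on hg38.

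Samples were grouped by their labels into 5 groups of 4. A letter in each sample code is undocumented and was treated as a possible batch. It is not balanced over the groups, and bortezomib replicates 2 and 4 are the only samples with theirs. Library totals ranged from 26797395 to 39710457 counts. Replicates were compared for duplicate deposition with a chi-square test of their counts. The closest pair, G2 replicates 3 and 4, had a chi-square per degree of freedom of 13.87 and the farthest, MG132 replicates 2 and 4, one of 651.63, so none was treated as a duplicate.

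The tests, groups, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where an alternative is said to have been chosen after seeing the data. Genes and repeat subfamilies were fitted together in R 4.3.3 with edgeR 4.0.16, with the filter filterByExpr, TMM scaling and the robust quasi-likelihood test (glmQLFit and glmQLFTest). All 20 libraries entered the fit with 1 mean per group, so that the groups shared 1 estimate of the spread with 15 residual degrees of freedom. The biological coefficient of variation was 33.3%. All adjusted p-values for single genes are from edgeR unless another tool is named, by the Benjamini-Hochberg method over 18959 genes and separately over 1076 repeat subfamilies, and a gene was called at an adjusted p under 0.05. The groups were compared as the report lists them, and log2 fold changes are given with their standard errors. Means ± SD are of CPM with TMM-adjusted library sizes, computed here from the deposited counts.

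Lists fixed in advance were proteasome subunits, cytosolic heat shock, ubiquitin and autophagy receptors, ATF4 amino acid response, ER chaperones and ERAD, NRF2 targets, metallothioneins, p53 targets, immediate early genes, NF-kB targets, G2/M genes, G1/S genes, sterol synthesis, histones, cytosolic ribosomal proteins, mitochondrial mRNAs, RNA polymerase III genes, RNA polymerase II subunits, fibroblast markers and leukocyte markers. The 17 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with an estimated correlation, and with fry, which tests whether a list moves one way on balance and compares it with no other genes. Named genes were, in each comparison, the 6 highest and the 6 lowest protein-coding called genes with a mean log2 CPM of at least 3 and no overlap between the groups' libraries, up to 4 members of each described list with the smallest p, and a set of stress, proteasome and cell cycle genes fixed in advance; of these the text gives those that carry each comparison, and some are not reported here. For repeats the 4 highest and 4 lowest called subfamilies at that level and a fixed set were eligible.

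Calls shared by MG132 and bortezomib came from a fit of their libraries and the G2 libraries, with 50 simulated draws of unchanged groups against the same controls and with the controls split. MG132-induced genes were selected on replicates 1 and 2 and measured on replicates 3 and 4, and the reverse. Alternatives fixed in advance were RLE, total library size and mitochondrial mRNA scaling (13 mRNAs), no filter, a strict filter (CPM of at least 1 in at least 4 samples), DESeq2 1.42.0, limma-voom, a fit of only the groups compared, genes and repeats fitted separately, a block for the replicate number, a block for the code letter, a 2-fold minimum, the other list tests and leaving out each library. An offset for GC content and gene length (prior count 2, loess span 0.5), the omission of the 4 GC-skewed libraries, the fit of all samples for shared calls, and leaving out each library for shared calls and MG132-induced genes were added after seeing the data. GC content and length were known for 98.6% of tested genes.

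The pipeline was tested on simulated counts drawn with the gene means and library sizes of all 20 libraries. Changes were set in MG132 and scored against G2 (18598 genes). edgeR recovered 19 of 99 genes changed 2-fold and 86 of 99 changed 4-fold, with 3 false calls. DESeq2 recovered 29 and 91 with 22 false calls, and limma-voom 19 and 87 with 6. With 8 libraries (17510 genes) edgeR recovered 5 of 92 and 77 of 92. When opposite GC trends were simulated in 2 libraries, from MG132 and from G2 (18646 genes), edgeR made 17 false calls without the offset and 13 with it. These were 13.8% and 10.7% of its calls, against 2.8% without a trend. With such trends an adjusted p under 0.05 thus did not hold false calls to that share in this single simulation. In the data, slopes on GC content were -0.55 and 0.85 in MG132 replicates 2 and 4 and 0.35 in G2 replicate 2. Those of MG132 were opposite within the group, so the simulated shares need not carry over. By the recovered counts, changes near 2-fold were mostly not detectable at this spread.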

Results

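Total RNA was sequenced from HCT-116 cells, an established human colorectal cancer line, to follow transcript levels when the proteasome is inhibited in cells synchronised in G2. The 20 samples formed 5 groups of 4. Asynchronous cells were untreated. G2 cells had been held in 2 mM thymidine, which stalls DNA replication, for 16 h and released for 7 h. The other 3 groups received the same synchronisation and then 3 h of drug: 20 µM MG132, 100 nM bortezomib, or 20 µM MG132 with 50 µg/ml α-amanitin, a toxin that inhibits RNA polymerase II. MG132 and bortezomib both inhibit the proteasome. G2 cells were collected at 0 h of drug, and a vehicle group of 3 h was not analysed here, so each comparison of a drug with G2 also contains 3 h of cell cycle time. Comparisons among the drug groups were matched for time.

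Each library held between 26797395 and 39710457 counts over genes and repeat subfamilies, and 18959 genes and 1076 repeat subfamilies were tested. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. That spread was uneven. In each library, the deviation of genes from their mean over all 20 libraries was fitted on GC content and length. Such a slope also holds differences between groups. The slope on GC content exceeded 0.3 log2 units per 10 percentage points, in either direction, in 4 libraries. It was 0.57 in asynchronous replicate 3, 0.35 in G2 replicate 2, -0.55 in MG132 replicate 2 and 0.85 in MG132 replicate 4. Protein-coding genes took 67.6% of counts in asynchronous replicate 1 and 68.3% in G2 replicate 1, against 75.5% or more in every other library.

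**Figure D1:**
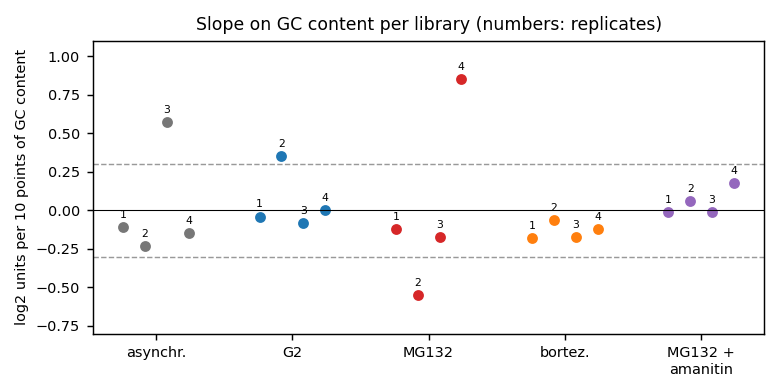
Slope on gene GC content of each library's deviation from the mean over all 20 libraries, in log2 units per 10 percentage points of GC. Each dot is 1 library and dashed lines mark 0.3 in either direction. The 4 libraries beyond the lines are asynchronous replicate 3, G2 replicate 2 and MG132 replicates 2 and 4.

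G2 cells were compared with asynchronous cells to show what the synchronisation itself changed. A few mitotic genes were called higher in G2 cells. KIF20A (ENSG00000112984.12; hg38 chromosome 5, 138178719 to 138187715), a kinesin needed for cytokinesis, rose from 139 ± 26.3 to 276 ± 25 CPM (counts scaled to a common library size; mean ± SD, n = 4; log2 fold change 0.99, SE 0.181, adjusted p = 0.00726). CDC25C, the phosphatase that activates the mitotic kinase CDK1, rose by 1.01 (adjusted p = 0.0118). CCNB1, which encodes cyclin B1, was at 598 ± 126 against 391 ± 74.5 CPM (n = 4) and did not pass (log2 fold change 0.61, adjusted p = 0.213), nor did the kinase gene PLK1 (0.27, adjusted p = 0.659). The steepest rise among well expressed protein-coding genes was that of DHRS2 (ENSG00000100867.15; chromosome 14, 23630115 to 23645639), a short-chain dehydrogenase, from 6.33 ± 3.48 to 66.8 ± 27.4 CPM (n = 4; log2 fold change 3.41, SE 0.393, adjusted p = 0.000363).

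Other genes higher in G2 cells included the α-tubulin gene TUBA1A (ENSG00000167552.14; chromosome 12, 49184796 to 49189324; log2 fold change 2.27, adjusted p = 0.00946), which has close paralogs and is uncertain to that extent. The ubiquitin ligase gene NEURL1B rose by 1.87 (adjusted p = 0.00849), the transglutaminase gene TGM2 by 1.53 (adjusted p = 0.00642) and the autophagy receptor gene OPTN by 1.35 (adjusted p = 0.00687). The glucose transporter gene SLC2A3 rose by 1.71 (adjusted p = 0.0138). E2F1 (ENSG00000101412.13; chromosome 20, 33675683 to 33686404), a transcription factor of the G1/S transition, fell from 38.2 ± 9.69 to 20.4 ± 3.47 CPM (n = 4; log2 fold change -0.90, SE 0.189, adjusted p = 0.015). The histone gene H4C1 was also lower (-2.21, adjusted p = 0.0224). Some calls depended on single libraries. SLC2A3 had an adjusted p of 0.052 without G2 replicate 4, and CDC25C 0.0579 without asynchronous replicate 4. E2F1 had 0.0576 without G2 replicate 1 and 0.0597 without G2 replicate 4, and it was not called with total library size scaling (adjusted p = 0.0655). H4C1 had 0.0976 without asynchronous replicate 1, and 0.056, 0.0703 and 0.0883 without G2 replicates 1, 3 and 4.

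Of the 28 genes of the G2/M list, 4 were called higher and 6 when adjusted over the list alone, with a median log2 fold change of 0.53 (camera adjusted p = 1.44e-08; adjusted p = 0.142 with an estimated correlation). Of 24 G1/S genes 1 was called lower and 4 when adjusted over the list alone (median -0.44, camera adjusted p = 1.38e-07; adjusted p = 0.32 with an estimated correlation). Histone genes had a median of -1.43, with 3 of 56 called lower and 39 when adjusted over the list alone (camera adjusted p = 3e-17; adjusted p = 0.783 with an estimated correlation). Histone genes took 2.453%, 0.351%, 1.966% and 0.96% of counts in asynchronous replicates 1 to 4, against 0.376% to 0.982% in G2, so replicates 1 and 3 stood above the G2 libraries and replicate 2 below each of them. Near-identical histone copies make single histone genes uncertain. No list called in this comparison held with an estimated correlation. Marker transcripts of other cell types were low: the fibroblast markers summed to 9.07 ± 1.94 CPM in G2 and 3.83 ± 0.435 in asynchronous cells, and the leukocyte markers to 3.05 ± 1.39 and 1.24 ± 0.479 (n = 4). Of each list of 10, at most 2 members passed the expression filter, and neither list was tested. Metallothionein genes, which share near-identical copies and were too few to test, summed to 527 ± 149 and 670 ± 417 CPM.

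In all, 397 genes differed between G2 and asynchronous cells, 369 higher and 28 lower, and 323 of them by at least 2-fold. The undocumented letter in each sample code was also entered as a block, and with it 110 genes were called. Scaling to total library size moved the median of all genes by 0.16 on the log2 scale and gave 677 calls, and scaling to mitochondrial mRNA gave 149. A fit of these 8 libraries alone called 8 genes. Of the genes named above as called, DHRS2 was the 1 still called in that fit, where TUBA1A had an adjusted p of 0.0675, H4C1 0.153 and the others 0.0636 to 0.182. KIF20A, TGM2, NEURL1B, OPTN, SLC2A3, CDC25C and E2F1 were not called with mitochondrial mRNA scaling (adjusted p = 0.188, 0.0568, 0.072, 0.072, 0.0935, 0.185 and 0.24). With the code letter block CDC25C (0.109) and H4C1 (0.0728) were not called, and H4C1 was not called with no filter (0.0712), limma-voom (0.0518) or the replicate block (0.0725) either. Without the 4 GC-skewed libraries 874 genes were called, and with an offset for GC content and length 1364, both chosen after seeing the data. Leaving out 1 library gave 205 calls without G2 replicate 1, 185 without G2 replicate 4, 243 without asynchronous replicate 2 and 143 without asynchronous replicate 4.

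MG132 was compared with G2 to show the response to proteasome inhibition. Cytosolic heat shock genes rose steeply. HSPA6 (ENSG00000173110.8; hg38 chromosome 1, 161524540 to 161526910), a strictly inducible HSP70, went from 0.125 ± 0.0637 to 75.6 ± 20.2 CPM (n = 4; log2 fold change 9.14, SE 0.483, adjusted p = 6.93e-10). HSPA1B (ENSG00000204388.7; chromosome 6, 31827735 to 31830255), the major inducible HSP70, rose from 356 ± 63.6 to 4396 ± 949 CPM (log2 fold change 3.63, SE 0.303, adjusted p = 4.15e-07). Its near-identical neighbour HSPA1A (ENSG00000204389.10; chromosome 6, 31815464 to 31817946) rose by 5.21 (adjusted p = 4.15e-07), and how reads were divided between the pair is uncertain. The co-chaperone genes DNAJB1 and BAG3 rose by 2.64 (adjusted p = 1.2e-06) and 2.61 (adjusted p = 6.12e-08). Of 28 cytosolic heat shock genes 14 rose and 22 when adjusted over the list alone (median 1.23, camera adjusted p = 1.35e-71; adjusted p = 6.31e-08 with an estimated correlation).

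Genes of the amino acid and integrated stress response driven by the transcription factor ATF4 rose with them, 13 of 25 and 22 when adjusted over the list alone, with 1 then lower (median 0.97, camera adjusted p = 8.75e-60). CHAC1 (ENSG00000128965.13; chromosome 15, 40952962 to 40956519), which degrades glutathione, rose from 2.07 ± 0.616 to 88.7 ± 17.5 CPM (n = 4; log2 fold change 5.42, SE 0.354, adjusted p = 1.75e-08). The stress-induced transcription factor gene ATF3 (ENSG00000162772.17; chromosome 1, 212565334 to 212620777) rose by 4.25 (SE 0.369, adjusted p = 5.79e-07). SESN2 rose by 3.52 (adjusted p = 6.12e-08), the pro-apoptotic factor gene DDIT3 by 3.16 (adjusted p = 4.77e-05) and the asparagine synthetase gene ASNS by 1.25 (adjusted p = 0.00106). Of 21 targets of the oxidative stress factor NRF2, 3 rose and 11 when adjusted over the list alone (median 0.66, camera adjusted p = 1.1e-20). Among them HMOX1 (ENSG00000100292.17; chromosome 22, 35380361 to 35394214), heme oxygenase 1, rose from 24.7 ± 11.6 to 437 ± 204 CPM (log2 fold change 4.15, SE 0.374, adjusted p = 8.75e-07), OSGIN1 by 3.21 (adjusted p = 2.17e-07) and SRXN1 by 1.40 (adjusted p = 0.00046). With an estimated correlation the ATF4 and NRF2 lists each had an adjusted p of 1.2e-05.

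Among 24 p53 targets 6 rose and 7 when adjusted over the list alone (median 0.47, camera adjusted p = 3.87e-12; adjusted p = 0.000432 with an estimated correlation). They included the cell cycle inhibitor gene CDKN1A (1.52, adjusted p = 0.00479) and GADD45A (2.56, adjusted p = 4.74e-07). MDM2, another p53 target, was not called (0.46, adjusted p = 0.83). It was at 53.65 CPM in MG132 replicate 4 and 312.9 to 337.6 in the other 3, and without that library its log2 fold change was 0.795 (adjusted p = 0.182). Of 23 immediate early genes 6 rose and 2 fell, 7 and 2 when adjusted over the list alone (median 0.41, camera adjusted p = 3.19e-13; adjusted p = 0.0238 with an estimated correlation). JUN (ENSG00000177606.7; chromosome 1, 58780788 to 58784327) rose by 4.67 (SE 0.419, adjusted p = 8.51e-07), the phosphatase gene DUSP1 by 2.46 (adjusted p = 2.66e-05) and IER5 by 1.60 (adjusted p = 0.000169). MYC was not called (-0.17, adjusted p = 0.882). Of 18 ubiquitin and autophagy receptor genes 4 rose and 6 when adjusted over the list alone (median 0.37, camera adjusted p = 3.58e-11; adjusted p = 1.84e-05 with an estimated correlation). The autophagy receptor gene SQSTM1 was at 535 ± 203 against 288 ± 57 CPM (n = 4) without passing (0.89, adjusted p = 0.0633). ZFAND2A (ENSG00000178381.12; chromosome 7, 1152071 to 1160759), which encodes a proteasome-associated zinc finger protein, rose by 4.50 (SE 0.312, adjusted p = 3.5e-08).

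None of the 34 proteasome subunit genes was called by edgeR in MG132-treated cells against G2, either over all genes or when adjusted over the list alone, among 2238 genes with an unadjusted p under 0.05. PSMD12 had a log2 fold change of 0.49 (adjusted p = 0.716) and PSMA3 one of 0.11 (adjusted p = 0.969). Their median was 0.14 (camera adjusted p = 0.012; adjusted p = 0.659 with an estimated correlation). The regulators of proteasome and antioxidant genes NFE2L1 (0.14) and NFE2L2 (0.58, adjusted p = 0.679) were not called. ER chaperone and ERAD genes had 3 of 20 called, also 3 when adjusted over the list alone (median 0.30, camera adjusted p = 3.83e-05; adjusted p = 0.0552 with an estimated correlation), and HERPUD1, a component of ER-associated degradation, rose by 1.99 (adjusted p = 8.69e-05). Sterol synthesis genes had a median of 0.95, with 1 of 18 called higher and 7 when adjusted over the list alone (camera adjusted p = 3.89e-11; adjusted p = 0.0846 with an estimated correlation). G1/S genes had a median of 0.30, with 1 of 24 called higher and 2 when adjusted over the list alone (camera adjusted p = 1.59e-05; adjusted p = 0.164 with an estimated correlation). The G2/M list was not called (median -0.07, camera adjusted p = 0.497), nor were the NF-kB targets (-0.12, camera adjusted p = 0.189), the RNA polymerase II subunits (-0.04, camera adjusted p = 0.796) or the RNA polymerase III list (camera adjusted p = 0.707). Adjusted over their list alone, 3 NF-kB targets were lower and 1 higher, and fry called that list lower (adjusted p = 0.0286).

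Lower transcripts in MG132-treated cells included AXIN2 (ENSG00000168646.13; chromosome 17, 65528563 to 65561647), a negative regulator and target of Wnt signalling, which fell from 21 ± 5.9 to 5.89 ± 2.34 CPM (n = 4; log2 fold change -1.83, SE 0.341, adjusted p = 0.00531). The transcription factor gene SOX4 fell from 54.2 ± 5.79 to 20.3 ± 2.68 CPM (-1.42, SE 0.213, adjusted p = 0.000754). The homeodomain repressor gene TGIF1 (-1.35, adjusted p = 0.00364), the Wnt ligand gene WNT16 (-1.33, adjusted p = 0.000863) and the phosphodiesterase gene PDE4B (-1.27, adjusted p = 0.00951) were also lower. TGIF1 was no longer called with the offset for GC content and length (-1.05, adjusted p = 0.145), an alternative chosen after seeing the data. PDE4B was not called with the code letter as a block (adjusted p = 0.0723). When only these 8 libraries were fitted, AXIN2 (-1.78, adjusted p = 0.106), TGIF1 (0.0829), WNT16 (0.0741) and PDE4B (0.172) were not called.

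In all, 395 genes differed between MG132 and G2, 191 higher and 204 lower, 299 of them by at least 2-fold. Scaling changed that balance. RLE gave 198 higher and 132 lower. Total library size gave 144 and 333, with the median of all genes moved by -0.12, and mitochondrial mRNA gave 76 and 132, with a shift of -0.26. Scaled to mitochondrial mRNA, ASNS (0.99, adjusted p = 0.108), SRXN1 (adjusted p = 0.0766) and CDKN1A (1.27, adjusted p = 0.0866) were not called. With a block for the code letter 204 genes were called, in a fit of these 8 libraries alone 86 (then without ASNS, SRXN1 and CDKN1A, adjusted p = 0.0516, 0.0698 and 0.0574), and 327 (206 higher and 121 lower) without the 4 GC-skewed libraries, where CDKN1A (adjusted p = 0.075) was not. Leaving out 1 library gave 224 calls without MG132 replicate 1, 203 without replicate 3 and 673 without replicate 4. It gave 239, 216 and 244 without G2 replicates 1, 2 and 4.

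**Figure D2:**
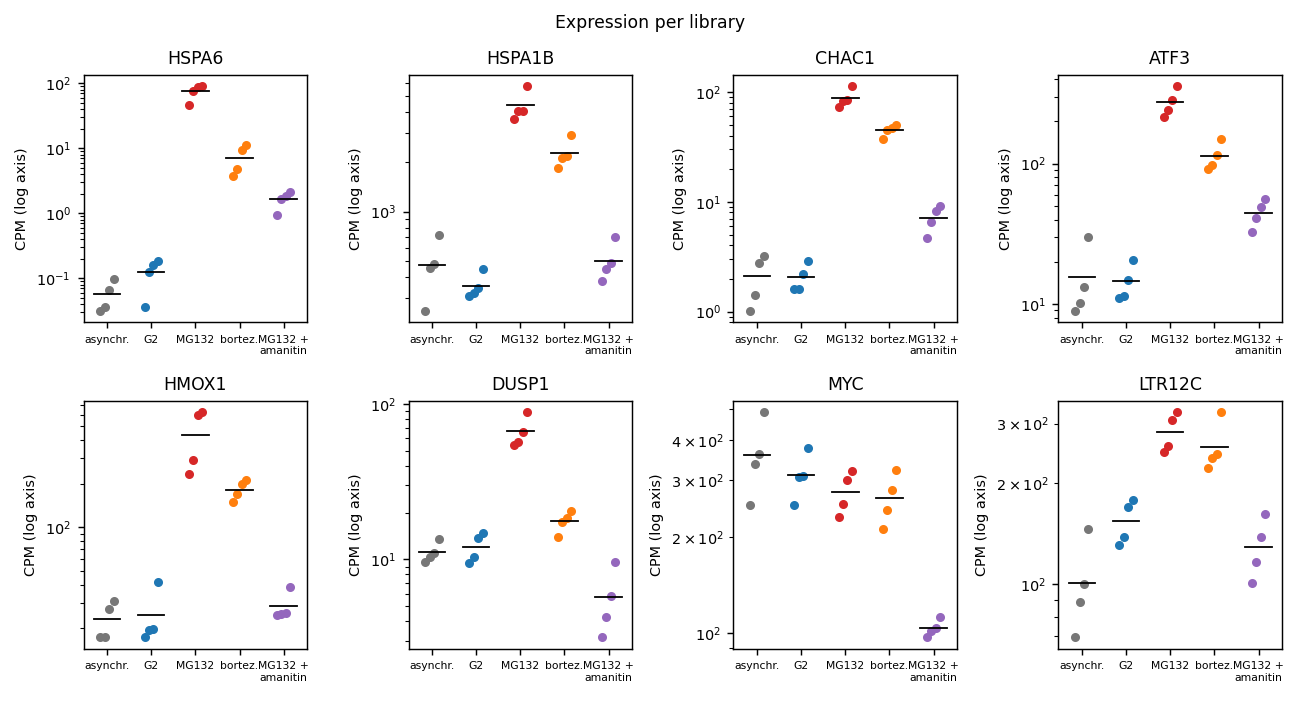
Level of 7 genes and of the repeat subfamily LTR12C in every library, in CPM on a logarithmic axis, by group; each dot is 1 of 4 libraries and each line is the group mean. HSPA6 averages 0.125 CPM in G2, 75.6 in MG132, 7.2 in bortezomib and 1.64 in MG132 with amanitin.

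Bortezomib was compared with G2 over the same 3 h, at 100 nM. Heat shock and stress response genes were again the leading increases. HSPA6 rose to 7.2 ± 3.53 CPM (n = 4; log2 fold change 5.75, SE 0.445, adjusted p = 3.95e-07) and HSPA1B to 2252 ± 472 CPM (2.66, adjusted p = 3.04e-05). CHAC1 rose to 45 ± 5.46 CPM (4.44, adjusted p = 3.95e-07), ATF3 to 114 ± 25.8 (2.97, adjusted p = 7.09e-05), JUN to 68.7 ± 13 (3.40, adjusted p = 6.82e-05) and HMOX1 to 182 ± 28.6 (2.88, adjusted p = 0.000117). DDIT4 (ENSG00000168209.5; chromosome 10, 72273920 to 72276036), an inhibitor of mTORC1 signalling, rose from 18.7 ± 12.7 to 185 ± 73.2 CPM (3.31, adjusted p = 0.00207).

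Of 28 cytosolic heat shock genes 7 rose with bortezomib and 13 when adjusted over the list alone (median 0.97, camera adjusted p = 5.47e-25; adjusted p = 9.85e-05 with an estimated correlation). Of 25 ATF4 genes 8 rose and 15 when adjusted over the list alone (median 0.66, camera adjusted p = 1.9e-24; adjusted p = 0.00176 with an estimated correlation). The secreted glycoprotein gene STC2 rose by 1.97 (adjusted p = 0.000117) and SESN2 by 2.69 (adjusted p = 6.19e-06). The NRF2 list had 3 of 21 called higher and 7 when adjusted over the list alone (median 0.30, camera adjusted p = 3.45e-07; adjusted p = 0.00366 with an estimated correlation). The p53 list had 3 of 24 and 5 when adjusted over the list alone (median 0.56, camera adjusted p = 6.8e-07; adjusted p = 0.00813 with an estimated correlation), and ubiquitin and autophagy receptors 2 of 18 and 4 (median 0.43, camera adjusted p = 9.92e-06; adjusted p = 0.00176 with an estimated correlation). NF-kB targets moved lower as a list, with 0 of 17 called by edgeR and 3 when adjusted over the list alone (median -0.36, camera adjusted p = 0.00171; adjusted p = 0.0185 with an estimated correlation). The proteasome subunits were not called as a list (median -0.03, camera adjusted p = 0.903). Immediate early genes had 2 called higher and 1 lower, 3 and 4 when adjusted over the list alone (median -0.16, camera adjusted p = 0.903).

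Lower transcripts with bortezomib included the circadian repressor gene NR1D1 (-1.79, adjusted p = 0.00922), TENT5B (-1.51, adjusted p = 0.00518), FJX1 (-1.45, adjusted p = 0.00211) and the small GTPase gene GEM (-1.40, adjusted p = 0.00665). JUNB, an AP-1 subunit, was lower by the same test (-1.51, adjusted p = 0.0109), but its adjusted p was 0.0546 without G2 replicate 1, 0.0554 without bortezomib replicate 1 and 0.0584 without bortezomib replicate 4. None of these lower genes was called with the code letter as a block, where their adjusted p ranged from 0.414 for TENT5B to 0.694 for JUNB.

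In all, 218 genes differed between bortezomib and G2, 93 higher and 125 lower, 178 of them by at least 2-fold. Scaling to total library size gave 74 higher and 171 lower, and scaling to mitochondrial mRNA gave 43 and 56 with the median of all genes moved by -0.21. The block for the code letter left 30 calls, all higher. Without the 4 GC-skewed libraries 425 genes were called. Leaving out 1 library gave 91, 97 and 137 calls without G2 replicates 1, 2 and 4, and 88, 120 and 109 without bortezomib replicates 1, 2 and 4.

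Genes changed by both inhibitors were counted in a fit of the 12 libraries of these 3 groups. Of 18050 genes tested, 88 were called in the same direction with each inhibitor, 51 higher and 37 lower, and 0 in opposite directions. Independent lists of the same sizes would share 0.444 higher and 0.289 lower genes. The comparisons share their G2 libraries, and 50 simulated draws of unchanged groups against those controls gave a median and a maximum of 0 shared calls, but 48 of the draws had no call in either comparison and none had calls in both, so this 0 says little about the 88. Neither value contains both the real effects and the shared controls. With the controls split, 23 genes were shared, all higher, in one assignment of G2 replicates and 32, of which 30 higher, in the other.

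Log2 fold changes correlated across genes with Pearson's r of 0.733 (genes are not independent replicates), inside the simulated range, whose median was 0.548 and highest 0.889. The covariance was 0.204 against a simulated median of 0.0724 and highest of 0.373, a difference from the median of 0.132. With split controls r was 0.588 and 0.0247, and the covariance 0.19 and 0.012. The count of shared calls was sensitive to single libraries. It was 48, 43 and 277 without MG132 replicates 1, 3 and 4, 42, 32, 32 and 30 without G2 replicates 1, 2, 3 and 4, and 29, 37, 52 and 40 without bortezomib replicates 1, 2, 3 and 4. The replicate block left 18 shared calls, all higher, and the block for the code letter 1. Without the 3 GC-skewed libraries of these groups 198 were shared, with the offset for GC content and length 285, and in a fit of all 20 samples 150, each chosen after seeing the data.

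MG132, a peptide aldehyde, and bortezomib, a peptide boronic acid, were compared directly after 3 h at their different doses. Few single genes separated them, and those that did were higher with MG132. HSPA6 was higher by 3.39 on the log2 scale (SE 0.347, adjusted p = 9.66e-05), at 75.6 ± 20.2 against 7.2 ± 3.53 CPM (n = 4). DUSP1 (ENSG00000120129.6; chromosome 5, 172768090 to 172771195) was at 66.4 ± 15.6 against 17.5 ± 2.71 CPM (1.92, SE 0.276, adjusted p = 0.00947) and ZFAND2A at 336 ± 58.7 against 91.8 ± 24 (1.87, adjusted p = 0.01). Other calls were the small heat shock protein gene CRYAB, named after its values were seen because its level was low, at 3.04 ± 0.954 against 0.149 ± 0.0671 CPM (4.31, SE 0.569, adjusted p = 0.0132), the collagen chaperone gene SERPINH1 (1.35, adjusted p = 0.0217) and the nuclear receptor gene NR4A1 (1.27, adjusted p = 0.047). Differences for HSPA1B (0.97, adjusted p = 0.779), DNAJB1 (1.00, adjusted p = 0.387), CHAC1 (0.98, adjusted p = 0.872) and HMOX1 (1.26, adjusted p = 0.617) did not pass, which does not show that the inhibitors act alike on them.

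By list, cytosolic heat shock genes were higher with MG132 than with bortezomib, 3 of 28 called and 11 when adjusted over the list alone (median 0.30, camera adjusted p = 1.44e-20; adjusted p = 0.000159 with an estimated correlation). Immediate early genes had 2 of 23 called higher, and 12 higher and 1 lower when adjusted over the list alone (median 0.73, camera adjusted p = 7.61e-23; adjusted p = 0.00827 with an estimated correlation). The ATF4 list had no gene called by edgeR and 4 when adjusted over the list alone (median 0.34, camera adjusted p = 2.02e-11; adjusted p = 0.0255 with an estimated correlation). The NRF2 list likewise had none and 3 (median 0.26, camera adjusted p = 8.18e-06; adjusted p = 0.0149 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.42 (camera adjusted p = 1.44e-20; adjusted p = 0.258 with an estimated correlation) and the RNA polymerase III list one of 0.58 (camera adjusted p = 9.96e-05; adjusted p = 0.258 with an estimated correlation).

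The 7 genes called between MG132 and bortezomib stood among 768 with an unadjusted p under 0.05, DESeq2 called 19 and limma-voom 7. Scaling to total library size gave 4 calls, and scaling to mitochondrial mRNA 3. A fit of these 8 libraries alone gave 3. SERPINH1 and NR4A1 were lost in all 3 of these (SERPINH1 adjusted p = 0.0539, 0.795 and 0.482; NR4A1 0.498, 1 and 0.482), DUSP1 with mitochondrial mRNA scaling (0.142) and ZFAND2A in the fit of 8 libraries (0.11). With the replicate block CRYAB (0.0993), SERPINH1 (0.0993) and NR4A1 (0.138) were lost, and NR4A1 also with the strict filter (0.0527) and limma-voom (0.0633). Without the 4 GC-skewed libraries 5 were called, and DUSP1 (adjusted p = 0.0825) and ZFAND2A (0.137) were not. With the code letter as a block, 0 were called by edgeR (327 unadjusted), and HSPA6 then had an adjusted p of 0.349. The count was 4 without MG132 replicate 4, and 3, 3, 1 and 1 without bortezomib replicates 1, 2, 3 and 4. HSPA6 was called in each of these fits, with an adjusted p of at most 0.0014. DUSP1 was lost without bortezomib replicates 2, 3 and 4 (adjusted p = 0.0528, 0.0647 and 0.0796), and ZFAND2A without replicates 3 and 4 (0.0998 and 0.0912). CRYAB was lost without any 1 of the bortezomib replicates (0.0533, 0.0999, 0.11 and 0.113). SERPINH1 and NR4A1 were each lost without MG132 replicates 1, 3 and 4 (SERPINH1 0.106, 0.0709 and 0.0809; NR4A1 0.135, 0.13 and 0.19) and without bortezomib replicates 1 to 4 (SERPINH1 0.0533, 0.11, 0.176 and 0.187; NR4A1 0.212, 0.184, 0.176 and 0.381).

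Adding α-amanitin to MG132 for the same 3 h asked which of these transcripts need RNA polymerase II. Levels are shares of each library, so a fall common to most transcripts under amanitin would not show. Against MG132 alone, the stress genes were far lower relative to other transcripts. HSPA6 was lower by 5.53 on the log2 scale (log2 fold change -5.53, SE 0.388, adjusted p = 1.32e-07). HSPA1B was at 505 ± 136 against 4396 ± 949 CPM (n = 4; -3.12, adjusted p = 1.57e-06), HMOX1 at 28.3 ± 6.7 against 437 ± 204 (-3.95, adjusted p = 1.49e-06) and CHAC1 at 7.13 ± 1.97 against 88.7 ± 17.5 (-3.64, adjusted p = 1.05e-06). DDIT4 was at 11.3 ± 5.25 against 309 ± 141 CPM (-4.78, SE 0.553, adjusted p = 2.35e-05) and GDF15, a stress-induced cytokine gene (ENSG00000130513.6; chromosome 19, 18374731 to 18389176), at 15.3 ± 3.97 against 186 ± 56 (-3.60, adjusted p = 6.24e-06).

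Immediate early genes were lower as a group with amanitin, 15 of 23 and 18 when adjusted over the list alone (median -1.26, camera adjusted p = 2.62e-53; adjusted p = 6.74e-05 with an estimated correlation). DUSP1 was at 5.72 ± 2.85 against 66.4 ± 15.6 CPM (n = 4; -3.54, adjusted p = 7.76e-07), FOS fell by 2.17 (adjusted p = 0.00191), and IER5 (-2.77, adjusted p = 4.96e-07) and MYC (-1.41, adjusted p = 0.000395) were lower. Of 28 cytosolic heat shock genes 11 were lower and 18 when adjusted over the list alone (median -1.22, camera adjusted p = 2.09e-47; adjusted p = 1.01e-06 with an estimated correlation). The ATF4 list had 11 of 25 lower and 18 when adjusted over the list alone (median -0.96, camera adjusted p = 1e-40; adjusted p = 6.74e-05 with an estimated correlation). The p53 list had 7 of 24 and 10 (median -0.53, camera adjusted p = 1.94e-10; adjusted p = 0.000858 with an estimated correlation), with CDKN1A lower by 1.68 (log2 fold change -1.68, adjusted p = 0.00154). NRF2 targets had 4 of 21 and 9 when adjusted over the list alone (median -0.53, camera adjusted p = 3.38e-12; adjusted p = 0.000228 with an estimated correlation). Mitochondrially encoded mRNAs had none of 13 called by edgeR and a median of 0.58 (camera adjusted p = 0.0317; adjusted p = 0.467 with an estimated correlation), and the RNA polymerase III list none of 10 and a median of -0.32 (camera adjusted p = 0.0329; adjusted p = 0.467 with an estimated correlation). ER chaperone and ERAD genes had 3 of 20 lower and 4 when adjusted over the list alone (median -0.15, camera adjusted p = 0.000416; adjusted p = 0.0887 with an estimated correlation).

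**Figure D3:**
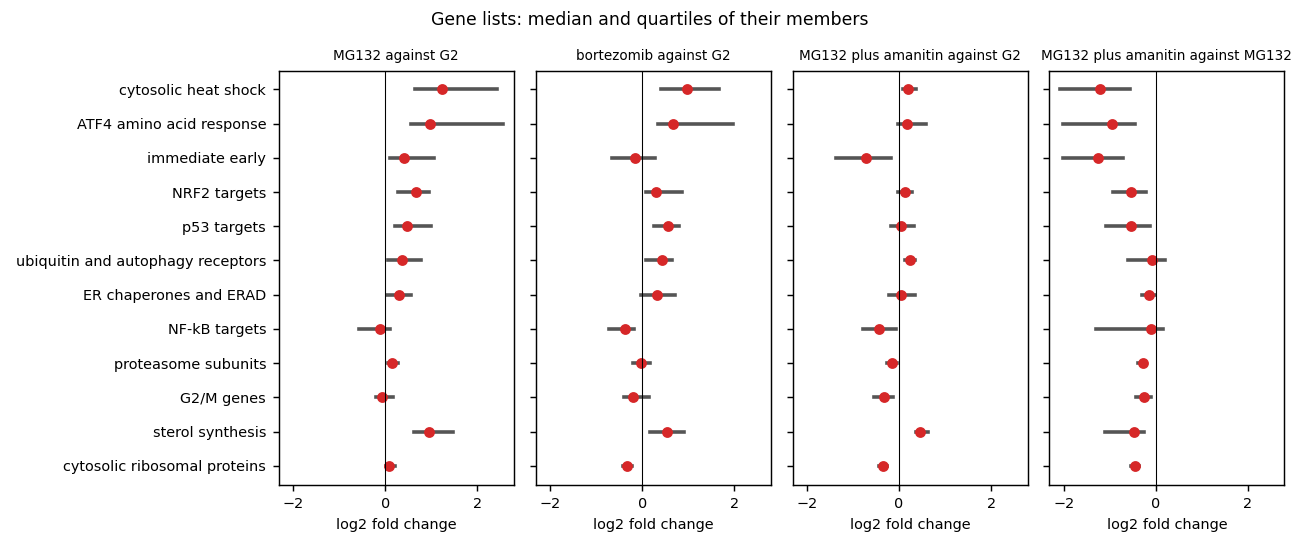
Median (red dot) and quartiles (grey bar) of the log2 fold changes of the members of 12 gene lists, in 4 comparisons. The cytosolic heat shock list has a median of 1.23 for MG132 against G2, 0.97 for bortezomib against G2, 0.20 for MG132 with amanitin against G2 and -1.22 for MG132 with amanitin against MG132.

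To measure the effect of amanitin on MG132-induced genes without reusing the libraries that selected them, genes called higher by MG132 in one pair of replicates were measured in the other pair. The 108 genes selected on replicates 1 and 2 had a median log2 fold change of -1.44 with amanitin against MG132 in replicates 3 and 4. Of these 92.6% were lower and 48.1% called lower. The 89 genes selected on replicates 3 and 4 had a median of -1.56, 100% lower and 48.3% called. The medians of all genes were 0.09 and 0.02. The mean of both medians, -1.50, was -1.71 with total library size and -2.15 with mitochondrial mRNA scaling, -2.37 with the replicate block and -2.58 with the code letter block. It was -0.42 without MG132 replicate 3 and between -1.96 and -1.42 without any 1 of the other 11 libraries, fits chosen after seeing the data.

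In all, 415 genes differed when amanitin was added, 129 higher and 286 lower, 356 of them by at least 2-fold. Of the genes called higher only 3 reached the level set for naming, ABCA2 (1.02, adjusted p = 0.0433), NLGN2 (0.97, adjusted p = 0.0499) and GJA3 (0.91, adjusted p = 0.0384). ABCA2 was lost without any 1 library other than MG132 replicate 4, with an adjusted p of up to 0.173. NLGN2 was lost without amanitin replicate 1, 2 or 4 or MG132 replicate 2 or 3, with up to 0.208, and GJA3 without amanitin replicate 1, 2 or 4 or MG132 replicate 1, 2 or 4, with up to 0.125. These calls also depended on scaling. ABCA2 and NLGN2 were lost with RLE (adjusted p = 0.0556 and 0.0632), total library size (0.0586 and 0.0591) and mitochondrial mRNA scaling (0.423 and 0.429), and GJA3 with mitochondrial mRNA scaling (0.395). All 3 were lost in the fit of these 8 libraries (0.0969, 0.233 and 0.151), with the replicate block (0.0811, 0.0811 and 0.0691) and without the 4 GC-skewed libraries (0.0551, 0.0828 and 0.197), ABCA2 and NLGN2 with the strict filter (0.0854 and 0.0924), NLGN2 and GJA3 with no filter (0.058 and 0.0612), and NLGN2 with the code letter block (0.0909). Total library size scaling gave 152 higher and 215 lower, with the median of all genes moved by 0.17, and mitochondrial mRNA scaling gave 44 and 240, with a shift of -0.15. The strict filter gave 42 and 242, the replicate block 72 and 216 and the code letter block 63 and 246. A fit of these 8 libraries alone called 189. Without the 4 GC-skewed libraries 57 were called higher and 368 lower, with 211 of the 415 still called. Leaving out 1 library gave 186 calls without amanitin replicate 1, 228 without amanitin replicate 2 and 268 without MG132 replicate 3.

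MG132 with amanitin was last compared with G2, which sets each transcript against the start of treatment. These levels too are shares of a library, and with TMM the median log2 fold change of all genes was -0.004. A fall common to most transcripts under amanitin would thus not show. Higher, lower and not called are here relative to the other transcripts. HSPA6 was above its G2 level at 1.64 ± 0.495 CPM (n = 4; log2 fold change 3.61, SE 0.444, adjusted p = 8.72e-05). CHAC1 (1.78, adjusted p = 0.00251), ATF3 (1.63, adjusted p = 0.00785), OSGIN1 (1.24, adjusted p = 0.0051), ZFAND2A (1.28, adjusted p = 0.011) and GADD45A (1.09, adjusted p = 0.00482) were also higher than in G2. HSPA1B (0.50, adjusted p = 0.434), HSPA1A (0.44, adjusted p = 0.671), DNAJB1 (-0.00, adjusted p = 0.999), HMOX1 (0.20, adjusted p = 0.866) and BAG3 (0.59, adjusted p = 0.0881) were not called. The heat shock list had 2 of 28 called higher and 4 when adjusted over the list alone (median 0.20, camera adjusted p = 0.00369; adjusted p = 0.22 with an estimated correlation).

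Other genes lay below their G2 level with MG132 and amanitin. TRIB1 (ENSG00000173334.4; hg38 chromosome 8, 125430321 to 125438405), a pseudokinase gene, fell from 250 ± 12.4 to 48 ± 6.18 CPM (n = 4; log2 fold change -2.38, SE 0.207, adjusted p = 2.99e-06). NFKBIA (ENSG00000100906.11; chromosome 14, 35401511 to 35404749), the NF-kB inhibitor, fell from 30.5 ± 5.1 to 5.79 ± 2.79 CPM (-2.40, SE 0.294, adjusted p = 8.72e-05). The Wnt antagonist gene DKK1 (ENSG00000107984.10; chromosome 10, 52314296 to 52318042) fell from 314 ± 94.9 to 60.1 ± 11.4 CPM (-2.39, adjusted p = 0.000116), and MYC from 312 ± 51.7 to 104 ± 6.43 CPM (-1.59, SE 0.209, adjusted p = 0.000172). ID1 (-2.36, adjusted p = 0.00305), SERTAD3 (-2.02, adjusted p = 0.00122), JUNB (-1.92, adjusted p = 0.00088), IER3 (-1.92, adjusted p = 0.000192), DUSP2 (-1.84, adjusted p = 5.4e-05) and ZFP36 (-1.77, adjusted p = 0.000403) were lower too. Immediate early genes had 2 higher and 11 lower of 23, 2 and 14 when adjusted over the list alone (median -0.71, camera adjusted p = 2.13e-14; adjusted p = 0.0436 with an estimated correlation). NF-kB targets had 3 of 17 lower and 5 when adjusted over the list alone (median -0.43, camera adjusted p = 0.000187; adjusted p = 0.0345 with an estimated correlation). POLR2A, which encodes the amanitin-binding subunit of RNA polymerase II, was not called (0.64, adjusted p = 0.23).

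In all, 636 genes differed between MG132 with amanitin and G2, 197 higher and 439 lower, 539 of them by at least 2-fold. Mitochondrial mRNA scaling gave 84 higher and 899 lower, with the median of all genes moved by -0.41, and under it ATF3 (1.22, adjusted p = 0.1), ZFAND2A (0.88, adjusted p = 0.106), OSGIN1 (0.86, adjusted p = 0.126) and GADD45A (0.72, adjusted p = 0.183) were not called. The code letter block left 224 calls, without ID1 (-1.96, adjusted p = 0.0904). Without the 4 GC-skewed libraries 881 were called. Leaving out 1 library gave 297 calls without amanitin replicate 1, 335 without amanitin replicate 2, and 348 and 374 without G2 replicates 1 and 2.

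Repeat subfamilies, each summed over its genomic copies and so without a single position, gave few calls. The endogenous retroviral subfamily HERV9NC-int rose with bortezomib from 29.3 ± 7.09 to 78 ± 19.1 CPM (n = 4; log2 fold change 1.41, SE 0.232, adjusted p = 0.00663), the 1 call of that comparison among 495 subfamilies with an unadjusted p under 0.05, where DESeq2 called 199 and limma-voom 1. The median of LINE subfamilies there was 1.03, and repeats took 9.59 ± 2.53% of counts with bortezomib, against 6.02% to 8.79% in the G2 libraries, with 13.1% in bortezomib replicate 4. HERV9NC-int was not called with total library size scaling (1.34, adjusted p = 0.11), with mitochondrial mRNA scaling (1.23, adjusted p = 0.291), in a fit of these 8 libraries alone (1.35, adjusted p = 0.0621) or with repeats fitted apart from genes (0.43, adjusted p = 0.599). With amanitin it was lower than with MG132 alone (-1.16, SE 0.231, adjusted p = 0.0177), as was LTR12C, the long terminal repeat of the HERV9 group, at 129 ± 26.5 against 284 ± 37.5 CPM (-1.14, SE 0.225, adjusted p = 0.0177). LTR12C was not called for MG132 against G2 (0.88, adjusted p = 0.437). The calls of HERV9NC-int and LTR12C with amanitin were lost without amanitin replicate 2 (adjusted p = 0.0537 for both), replicate 3 (0.0557 and 0.0738) or replicate 4 (0.0539 for both), or without MG132 replicate 3 (0.0692 for both). They were also lost in a fit of those 8 libraries alone (0.218 for both) and with the code letter as a block (0.0598 for both), and that of HERV9NC-int with the replicate block (0.0533) and with total library size (-1.0, SE 0.28, adjusted p = 0.152) and mitochondrial mRNA scaling (-1.32, SE 0.32, adjusted p = 0.0694), with the SE larger under both, while LTR12C was called under both (-0.96, adjusted p = 0.0367, and -1.30, 0.0314).

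For MG132 against G2, edgeR called 0 subfamilies, with 21 at an unadjusted p under 0.05, and DESeq2 4 and limma-voom 0. For MG132 against bortezomib, edgeR called 0 with 121 unadjusted, and DESeq2 and limma-voom also 0. G2 against asynchronous cells gave 1 call of 25 unadjusted, HERV9-int (1.75, adjusted p = 0.019), named after its value was seen and lost in 5 of 8 leave-one-out fits, with adjusted p of 0.0794, 0.102 and 0.078 without asynchronous replicates 1, 2 and 3 and 0.0839 and 0.113 without G2 replicates 2 and 4. It was also lost with limma-voom (0.0587), repeats fitted apart from genes (0.0554), the replicate block (0.0623) and the code letter block (0.213), in the fit of 8 libraries (0.153) and without the 4 GC-skewed libraries (0.409). MG132 with amanitin against G2 gave 1 call, MER89-int (2.86, adjusted p = 0.0279), lost without amanitin replicates 1 and 2 (0.153 and 0.0822) and without any 1 of the G2 replicates 1 to 4 (0.102, 0.18, 0.0691 and 0.0756), and with mitochondrial mRNA scaling (0.1), no filter (0.0783), the replicate block (0.149) and the code letter block (0.462). Amanitin against MG132 gave 7 of 73 unadjusted. Besides LTR12C and HERV9NC-int these were LTR4, lower (-1.30), and, higher, MER89-int (2.30), ACRO1 (2.94), HERV15-int (1.42) and LTR10G (1.51), of which LTR4, ACRO1, HERV15-int and LTR10G are named after their values were seen. MER89-int was there lost in 6 of 8 leave-one-out fits, without MG132 replicates 2, 3 and 4 or amanitin replicates 1, 2 and 3 (adjusted p of 0.0557 to 0.194). It was also lost with mitochondrial mRNA scaling (0.0694), no filter (0.0884), the replicate block (0.102) and the code letter block (0.144), in the fit of these 8 libraries (0.243) and without the 4 GC-skewed libraries (0.28). The count was 12, 4, 0 and 3 without MG132 replicates 1, 2, 3 and 4, and 1 and 3 without amanitin replicates 2 and 3. DESeq2 called 12 there and limma-voom 9.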

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

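No test of an explanation was run for the values in this part, and no biological explanation was tested, since the design gives none within a group. A library was listed when its gap to the nearest of the other 3 exceeded Dixon's 95% critical share of the group's range, a limit that chance passes in about 1 of 20 groups; 7 of 70 library measures and 26 of 430 gene groups passed it.

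Among library measures, the protein-coding share was 67.6% in asynchronous replicate 1 (80.1% to 80.7% in the others) and 68.3% in G2 replicate 1 (80.2% to 82.2%). The GC slope was 0.57 in asynchronous replicate 3, against -0.23 to -0.11. The mitochondrial mRNA share was 0.793% in G2 replicate 1, where the others had 1.2% or more, and 1.39% in MG132 replicate 1, where the others had at most 1.15%. MG132 replicate 3 had the deepest library at 39.7 M counts, and miscellaneous RNA took 7.05% of MG132 replicate 4.

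Among genes, in CPM, G2 replicate 1 stood above its group for TUBA1A (155, against 51.6 to 66.5), PSMA3 (216.5), DDIT4 (37.7) and IER3 (292.6). G2 replicate 2 stood above it for E2F1 (25.6), CDC6 (194.3), HMOX1 (42), MFSD5 (30.1) and SRXN1 (85.4), and below it for NFE2L2 (44.3). Asynchronous replicate 2 was high for FOS (17.5) and HERV9NC-int (20.4) and low for OSGIN1 (10.95), and asynchronous replicate 4 low for IER3 (211.4). With bortezomib, replicate 1 was high for HERPUD1 (157.1) and HERV9NC-int (106.5) and replicate 3 for NFKBIA (15.65). With MG132, replicate 4 was high for RSAD1 (35.6) and CDKN1A (523.6) and low for MDM2 (53.65, against 312.9 to 337.6), and replicate 2 was high for DKK1 (237.3). With MG132 and amanitin, replicate 4 was high for NEURL1B (27.85), HMOX1 (38.4), SOX4 (39.9) and OSGIN1 (41.8) and low for HERV9-int (5.72).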

How the results depend on the processing

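The offset, the omission of GC-skewed libraries, the fit of all 20 samples, and leaving out libraries for shared calls and MG132-induced genes were chosen only after the results were seen; all other alternatives were planned and all were run. No result changed direction in a call. Libraries held 26797395 counts or more, and what depth limits was not measured, since no alternative varied it. Below, gene counts are followed by those called higher and lower; totals not listed stayed within 1.5 times, and the cause of each move was not tested unless the setting itself uses fewer samples or genes. Order of comparisons: G2 against asynchronous cells, MG132 against G2, bortezomib against G2, MG132 with amanitin against G2, MG132 with amanitin against MG132, and MG132 against bortezomib.

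DESeq2 called 714 (578, 136), 647 (331, 316), 621 (264, 357), 1005 (371, 634), 718 (225, 493) and 19 genes, and 3, 4, 199, 18 and 12 repeat subfamilies in the first 5 comparisons. limma-voom called 0 subfamilies in G2 against asynchronous cells, where edgeR called 1. Total library size gave 677 genes (663, 14) for G2 against asynchronous cells, 4 for MG132 against bortezomib, 0 subfamilies for bortezomib, and -1.71 for MG132-induced genes under amanitin. Mitochondrial mRNA scaling gave 149 (146, 3), 208 (76, 132), 99 (43, 56), 983 (84, 899) and, for MG132 against bortezomib, 3 genes. It gave 0 subfamilies for bortezomib, 0 for amanitin against G2 and 3 for amanitin against MG132, and -2.15 for the induced genes. Without a filter, 2 subfamilies were called in G2 against asynchronous cells and 0 in amanitin against G2. The strict filter gave 249 genes (235, 14) for G2 against asynchronous cells and 396 (84, 312) for amanitin against G2. The split by direction moved by more than 1.5 times under some settings whose total did not. For amanitin against MG132, 129 higher genes became 44 with mitochondrial mRNA scaling, 42 with the strict filter, 72 with the replicate block, 63 with the code letter block and 57 without the 4 GC-skewed libraries. For MG132 against G2, 204 lower genes became 132 with RLE, 333 with total library size, 116 with no filter, 122 with the strict filter and 121 without the GC-skewed libraries. For G2 against asynchronous cells, 28 lower genes became 8 with no filter and 52 with repeats fitted apart from genes, and for amanitin against G2, 197 higher genes became 310 with the offset.

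A fit of only the 2 groups compared called 8 genes in G2 against asynchronous cells, 86 (81, 5) in MG132 against G2, 386 (122, 264) in bortezomib against G2, 189 (49, 140) in amanitin against MG132 and 3 in MG132 against bortezomib. It called 0 subfamilies in the first of these, in bortezomib against G2 and in amanitin against MG132. Repeats fitted apart from genes gave 0, 0, 24 and 55 subfamilies for G2 against asynchronous cells, bortezomib, amanitin against G2 and amanitin against MG132. The code letter block gave 110 (105, 5), 204 (144, 60), 30 (30, 0), 224 (70, 154) and, for MG132 against bortezomib, 0 genes by edgeR (327 unadjusted). It gave 0 subfamilies for G2 against asynchronous cells, 1 for MG132, and 0 and 0 for amanitin against G2 and against MG132, 1 shared call, and -2.58 for the induced genes.

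The replicate block gave 238 genes (231, 7) for G2 against asynchronous cells, 258 (141, 117) for MG132, 120 (58, 62) for bortezomib and 3 for MG132 against bortezomib. With the replicate block 0 subfamilies were called in G2 against asynchronous cells, 0 in amanitin against G2 and 3 in amanitin against MG132. Shared calls were 18 and the induced genes -2.37 with that replicate block. The numbers are not known to pair samples: deviations of 40 pairs with the same number correlated at -0.80 to 0.83 (median -0.01, 13 over 0.1), and 6 of 20 libraries correlated best with their own number.

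The GC and length offset gave 1364 genes (1090, 274), 1003 (458, 545), 641 (269, 372) and, for amanitin against MG132, 743 (266, 477) and MG132 against bortezomib 16 (15, 1), and 285 shared calls. Of the genes called in the 6 comparisons it still called 377 of 397, 371 of 395, 199 of 218, 519 of 636, 352 of 415 and 7 of 7. Without the 4 GC-skewed libraries 874 genes (706, 168) were called in G2 against asynchronous cells and 425 (176, 249) in bortezomib against G2, with 0, 2 and 2 subfamilies for G2 against asynchronous cells, bortezomib and amanitin against MG132, and 10 lists in the last. Without the 3 such libraries of their groups shared calls were 198 (112, 86), and in the fit of all 20 samples 150 (70, 80).

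Lists called were 6, 12, 12, 10, 16 and 13 with camera, and 0, 6, 6, 2, 7 and 5 with an estimated correlation. With fry they were 2 for G2 against asynchronous cells, 7 for bortezomib, 4 for amanitin against G2, 8 for amanitin against MG132 and 4 for MG132 against bortezomib.

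Leaving out each library in turn, gene counts ranged over 143 to 457, 203 to 673, 88 to 181, 297 to 679, 186 to 547 and 1 to 10 in the order above. Subfamilies ranged over 0 to 1, 0 to 0, 1 to 1, 0 to 2, 0 to 12 and 0 to 0, and lists over 4 to 9, 9 to 13, 8 to 14, 8 to 11, 13 to 16 and 10 to 15. Shared calls ranged from 29 to 277 and the induced genes from -1.96 to -0.42.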

Other observations

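In this part, the splits of the samples, the tests on gene class and gene length, and the tests on GC content, on genomic DNA and on the repeats were chosen only after the results were seen; the tests of scaling on genes were chosen before their results were seen.

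Small nucleolar and small nuclear RNAs were over-represented among the genes that fell when amanitin was added to MG132. Of 261 small nucleolar RNA genes tested 40 were lower and 0 higher (Fisher's exact test, two-sided, adjusted p = 3.16e-27 over 84 tests of gene class and direction), as were 22 of 88 small nuclear RNA genes (9.68e-20) and 12 of 210 microRNA genes (0.000404). Against G2, 52 of the 261 small nucleolar RNA genes were lower (2.63e-32). Many of these genes lie in introns of hosts or have near-identical copies, so the RNA counted on each is uncertain, and the genes of a class are not independent. Small nucleolar RNA took 0.887% and 0.815% of counts in the GC-skewed MG132 replicates 2 and 4. In MG132 replicates 1 and 3 it took 0.46% and 0.339%, inside the 0.283% to 0.666% with amanitin. Small nuclear RNA took 2.59% and 2.34% in the former, 1.419% and 1.465% in the latter, and 1.191% to 1.565% with amanitin. G2 replicate 1 had 1.098% and 4.006%. These tests were run under no alternative setting.

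Protein-coding genes called with amanitin against MG132 were shorter than those not called. The 151 called lower had a median span of 10 kb, the 74 called higher one of 22.7 kb and the 13530 not called one of 33.3 kb, and at a mean log2 CPM of at least 3 these medians were 10.9 kb, 21.7 kb (3 genes) and 35.5 kb. This is a description of the called genes, with no test of its cause. Libraries with amanitin had counts on 29915 ± 919 rows of the table on average, against 27803 ± 1010 with MG132 alone (n = 4).

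The first pattern weighed is the one-sided change between G2 and asynchronous cells, 369 genes higher and 28 lower. With the offset 1090 genes were higher and 274 lower (79.9% higher, against 92.9% without it). Without the 4 GC-skewed libraries 706 were higher and 168 lower (80.8%). The imbalance thus remained in both, which argues against GC content bias as its whole cause. On length only the offset speaks, since libraries were omitted by their GC slope alone. Asynchronous replicate 1 and G2 replicate 1, with length slopes of -0.45 and -0.29, stayed in. The imbalance was smaller with the offset and with the omission, so a part stays open. That 355 of the 369 (96.2%) were still called higher with the offset says little, because the offset removed 62.9% of within-group variance. Genomic DNA in the G2 libraries stays open. LINE subfamilies had a median of -0.42, but 1 of the 165 had an unadjusted p under 0.05, and subfamilies are not independent. Rows with counts went the other way, 28171 ± 879 in G2 and 26474 ± 889 in asynchronous cells (n = 4). Scaling stays open: the lowest median of these genes over 3 other scalings was 1.59 against 1.62 with TMM, but those scalings moved the median of all genes by at most 0.16, too little for that test to fail. Chance also stays open: in a fit of the 8 libraries alone, the real split called 8 genes and another split 3992, so that 2 of 35 splits called as many. That other split set G2 replicates 1 and 2 and asynchronous replicates 1 and 3, whose slopes on gene length were -0.29, -0.21, -0.45 and -0.16, against the rest (0.07 to 0.15), and points to a structure of the samples.

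The second pattern is that 90 of the 129 genes higher with amanitin than with MG132 alone were near silent, below 0 on the log2 CPM scale, with a median log2 fold change of 2.18. GC content stays open. The median of the 129 genes was 1.94 without the 4 GC-skewed libraries against 1.91 with all, but the genes were chosen as higher in libraries that this fit mostly kept. The skewed libraries of this comparison, MG132 replicates 2 and 4, also had opposite slopes (-0.55 and 0.85). Without the skewed libraries 57 genes were called higher, and only 38 of the 129 were still called, with fewer samples and a median SE of 0.491 against 0.416. With the offset, which also covers length, 112 of the 129 (86.8%) were still called. That says little, because the offset raised all calls from 415 to 743, so length stays open. Genomic DNA in the amanitin libraries stays open. All 4300 near-silent genes tested, called or not, had a median of 0.21 (quartiles -0.23 to 0.66), and LINE subfamilies had a median of 0.17. Summed reads of 102 olfactory receptor genes, scaled to library size, were 150, 123, 135 and 120 in amanitin replicates 1 to 4. In MG132 replicates 1 to 4 they were 153, 176, 171 and 61. These reads showed no rise with amanitin against MG132 replicates 1 to 3, only against replicate 4. Genes at so low a level exclude nothing, however. Scaling stays open too, since the 3 other scalings, with a lowest median of 1.74 (1.91 with TMM), moved the median of all genes by at most 0.17, too little for that test to fail, and mitochondrial mRNA scaling called 44 genes higher. An effect of amanitin itself also stays open and was not tested apart from these.

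The third pattern concerns the HERV9NC-int and LTR12C repeats. With bortezomib their mean log2 fold change against G2 was 1.07 (SE 0.227), which cannot be told apart from a general rise of repeat reads, because the quartiles of all LTR subfamilies were 0.67 and 1.01. Summed olfactory receptor reads, scaled to library size, were 315, 159, 199 and 309 in bortezomib replicates 1 to 4. In G2 replicates 1 to 4 they were 118, 87.9, 189 and 155. Genomic DNA in the bortezomib libraries was not tested, for repeats or for genes, and stays open. With amanitin against MG132 the mean of HERV9NC-int and LTR12C was -1.15 (SE 0.228), while the LTR quartiles were 0.20 and 0.63. That mean lay -1.55 from the LTR median, a distance that 1 factor per library leaves as it is. Both subfamilies are weighed here because they were called lower in this comparison, so a place below the quartiles was set by that choice. These values therefore decide neither on a general shift of repeat reads nor on scaling. That these subfamilies may be transcribed by RNA polymerase II during proteasome inhibition is a hypothesis found on these libraries and not tested on others. LTR12C was not called for MG132 against G2. Both calls with amanitin were lost in 4 of 8 leave-one-out fits, in a fit of those 8 libraries alone and with the code letter as a block. HERV9NC-int (-1.16, SE 0.231) was not called with total library size (-1.0, SE 0.28, adjusted p = 0.152) or mitochondrial mRNA scaling (-1.32, SE 0.32, 0.0694), where its SE was larger, while LTR12C was called under both (-0.96 and -1.30, adjusted p = 0.0367 and 0.0314).

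Other splits of the 8 libraries into 4 and 4 were also counted for the remaining comparisons, 35 splits each, the real one included, in fits of those libraries alone. For gene counts, 1 split of 35, the real one, called as many in 5 comparisons. This is the smallest share possible and was not adjusted for the 6 comparisons. It argues against chance for each comparison taken alone and does not exclude it. The counts were 86 for MG132 against G2, with 0 in the highest other split, and 386 for bortezomib against G2, with 0. They were 771 for amanitin against G2, with 15, and 189 for amanitin against MG132, with 0. The fifth was 3 for MG132 against bortezomib, with 0. The last rests on 3 calls, and in the fit of all 20 libraries its count of 7 fell to 1 without bortezomib replicate 3 or 4. The splits do not account for the code letter, which is unbalanced over groups, and with it as a block 0 genes were called between MG132 and bortezomib by edgeR (327 unadjusted; HSPA6 adjusted p = 0.349). For repeat subfamilies chance cannot be excluded. The real splits called 0, 0, 0, 1, 0 and 0 by edgeR in the order G2 against asynchronous cells, MG132, bortezomib and amanitin against G2, amanitin against MG132 and MG132 against bortezomib, and the highest others 934, 650, 813, 782, 397 and 748. As many calls were made by 35, 35, 35, 5, 35 and 35 splits, and those high counts point to a structure of the samples that affects repeats. Where the real split called 0 the count of splits says nothing more, and the 7 calls for amanitin against MG132 in the fit of all 20 libraries were not put to this test. For gene lists chance cannot be excluded either, with 6, 12, 12, 10, 16 and 12 called in the real splits, 11, 14, 14, 12, 16 and 15 in the highest others, and 19, 5, 5, 6, 3 and 3 splits with as many.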
